A study of Mus musculus with 6 samples.

How the data were processed

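Single cells were measured in 6 samples, 3 female and 3 male mice of genotype Ai14f/+;Sf1-Cre at postnatal day 10, each a plate of 96 wells. Per the labels' protocols, hypothalamus was dissected, dissociated with papain, sorted by fluorescence and made into libraries with the BD Precise whole transcriptome kit. The deposited values were whole-number counts per gene and well, not normalised and with no wells removed. HTSeq and the mm10 genome were named in the submitters' processing notes. Their versions, the aligner, the strand of counting, the treatment of reads that match several genes and whether counts were of molecules or reads are not given in the sources used here. The tables listed 21926 genes, and 1 symbol was in date form (6-Sep). Sequencing reads were not used here.

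Cells were kept with at least 500 detected genes and under 25% of counts in mitochondrial genes, and 46 wells were left out, all for few genes. Counts per kept cell were scaled to 10000 and logged, and Y-linked genes were left out of the clustering. The 2000 most variable genes were scaled within each mouse, since 1 of the 7 clusters made without this scaling held 80 of the 87 kept cells of female 2 and 1 other cell. Then 20 principal components and 10 nearest neighbours went into Leiden clustering (resolution 1, seed 7). The scaling was chosen after seeing the data. Other clusters made without it joined certain mice of both sexes. Of the 84 cells of 1 such cluster, 49 were from female 3 and 32 from male 3. Of the 126 cells of another, 31 were from female 1, 34 from male 1 and 58 from male 2. Numbers of 8, 12 and 15 neighbours were tried as well, and 10 was chosen before any sex difference within clusters was seen, because 12 and 15 left no astrocyte-like cluster. Clusters were named by lists of marker genes: a VMH neuron-like cluster needed 3 VMH markers in at least 20% of its cells, and an arcuate neuron-like cluster arcuate markers at 5 times the VMH markers. No doublet caller was run. Cluster levels were means over mice with at least 5 cells of the cluster. Intervals of shares were exact 95% binomial intervals, and a count of 0 was taken to allow 3 counts.

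Counts were summed over cells per mouse, since cells are not replicates, and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3. The tests were of the sex difference in all neurons, in Esr1-undetected neurons and within each cluster with at least 5 cells of every mouse (adjusted within the cluster). Others were of Esr1-detected against Esr1-undetected neurons with mouse as a block, and of the interaction of sex with Esr1 detection. Fold changes are log2, male over female or Esr1-detected over undetected, and CPM are counts scaled by each sum's total. Detection shares and cluster shares were compared with two-sided exact permutation tests over the 20 assignments of 6 mice, whose smallest p is 0.1. Gene lists (18, of which those with at least 3 tested genes were used) were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1 on voom values. DESeq2 1.42.0, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and Python 3.11.15 were also used. Thinning drew 2133 counts per neuron, the 10th percentile of neuron totals, and left out 44 neurons of female 2, 6 of female 1 and 1 each of males 1 and 3.

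The tests, lists, named-gene rule and 57 alternatives were fixed before the data were examined, and 11 alternatives were added after seeing the data. Alternatives were other tools, scalings and filters, other cell and detection limits, other clusterings, and leaving out each mouse. Genes were named by a rule with 4 parts. In sex comparisons, these were the tested members of the Y-linked, X-inactivation and escape, study-named and sex steroid lists. In all comparisons, these were up to 10 genes per direction with an adjusted p under 0.05, at least 20 CPM in a group and no overlap between the groups (for Esr1, the same direction in all 6 mice), by the size of the change. Where this gave under 3 genes, these were the 5 with the smallest p, as values that did not pass all conditions. Up to 4 members of each list that passed were named. Some genes that the rule names are not reported here. In the Esr1 comparison and the interaction, some genes named by that part had an adjusted p under 0.05 without the condition on single mice. Npy, Sst, Calb2, Lypd1 and Atraid in the Esr1 comparison, and genes describing clusters, were named after their values were seen. Xist, Jpx, Ftx, 5530601H04Rik, Sts and Dlx6os1 were not in the tables and were not analysed here. Positions are from GENCODE vM21 (GRCm38/mm10).

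The fits were tested on simulated counts with 200 changed genes. Each gene was drawn independently with 1 dispersion (spread between mice beyond counting error), the common value of the summed neurons (0.0833). The same value was used for the Esr1 comparison, the interaction and cluster 5, whose sums hold fewer cells. Genes and sums that vary more may be recovered less often, so the shares below may be too high for the data. In the sex comparison of neurons (6608 genes), 25.4, 94.0 and 100% of genes changed by 2, 4 and 8-fold were recovered, with 5 false calls. For the Esr1 comparison (3775 genes) the shares were 7.69, 68.3 and 93.2% with 5 false calls. For the interaction (3780 genes) they were 0, 9.52 and 32.3% with 0 false calls, and for cluster 5 (987 genes) 25, 71.0 and 100% with 4 false calls. A simulated list changed by 1.5-fold was called (adjusted p = 4.20e-32) and an unchanged list was not (0.943). As the genes were drawn independently, this does not test camera on lists whose genes vary together.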

Results

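Messenger RNA was counted in single cells of the ventromedial hypothalamus (VMH) of 6 mice at postnatal day 10, of which 3 were female and 3 male. The cells carried the Ai14f reporter switched on by Sf1-Cre, a driver for cells of the Nr5a1 (SF-1) lineage, and were sorted by fluorescence into 96 wells per mouse. The series title names estrogen receptor alpha signaling and a sexually dimorphic node of energy expenditure. The comparisons therefore concern the sexes and the neurons with and without a count of the receptor gene Esr1. Of 576 wells, 530 held at least 500 detected genes and were kept. The kept wells of the females numbered 88, 87 and 86 and held 441260, 185654 and 591768 counts. Those of the males numbered 93, 84 and 92 and held 783270, 535469 and 774670 counts. Female 2 was the shallowest, at a median of 2097 counts per kept cell, against 5170 and 6737.5 in females 1 and 3 and 5945 to 7979.5 in the males. Intervals and floors given for counts cover counting error only.

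Neurons made up 521 of the 530 cells and fell into 8 clusters, and 9 cells were astrocyte-like. Clusters 1, 2, 3, 4, 5 and 7 (457 cells) met the marker rule for VMH neurons. Cluster 1 (128 cells) was led by Fezf1, a zinc finger transcription factor of the VMH, with a count in 64.8% of its cells and 325 ± 148 CPM (SD, n = 6 mice). Cluster 2 (95 cells) held Krt18 (113 ± 36.6 CPM), the neurofilament gene Nefm (233 ± 48.2 CPM) and the highest shares of cells with Nr5a1 (64.2%) and the dynorphin precursor gene Pdyn (85.3%; 429 ± 179 CPM) among the 8 clusters. The vesicular glutamate transporter gene Slc17a6 was in 91.6% of its cells and 95.8% of those of cluster 7. Cluster 3 (92 cells) was led by Tcf7l2, Prdm13 (122 ± 92.4 CPM) and Bcl11b (123 ± 64.3 CPM). Cluster 4 (63 cells) was led by Cartpt, Bcl11a and Dkk3 (113 ± 27.7 CPM, n = 5 mice). In it, 71.4% of cells held Tac1, the precursor gene of substance P, at 1898 ± 466 CPM. Cluster 5 (55 cells) was led by Nfix (180 ± 84.3 CPM) and Nfib (111 ± 95.6 CPM), and 52.7% of its cells held Sox14 against 3.17% in cluster 4. Cluster 6 (42 cells) held the peptide genes Gal (1285 ± 1590 CPM) and Penk (552 ± 775 CPM) with the GABA synthesis gene Gad1 (165 ± 161 CPM) and no Nr5a1 count. It met no marker rule beyond that for neurons. Cluster 7 (24 cells) was led by Zbtb4 and Rev1. Cluster 8 (22 cells) was arcuate neuron-like, with Pomc at 11072 ± 2844 CPM (n = 3 mice), Tbx3 at 210 ± 55.6 CPM and Isl1 in 81.8% of its cells. Tac1 was at 707 ± 305, 709 ± 396 and 1054 ± 1161 CPM in clusters 1, 2 and 3 and at 68.2 ± 41.0 CPM in cluster 5 (n = 6 mice each). The p53 target gene Rprm was at 335 ± 186 CPM in cluster 4 (n = 5 mice), 243 ± 131 in cluster 1 and 76.3 ± 74.7 in cluster 2. Adcyap1 was at 263 ± 124 CPM in cluster 3 and 2.76 ± 6.77 in cluster 5.

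**Figure D1:**
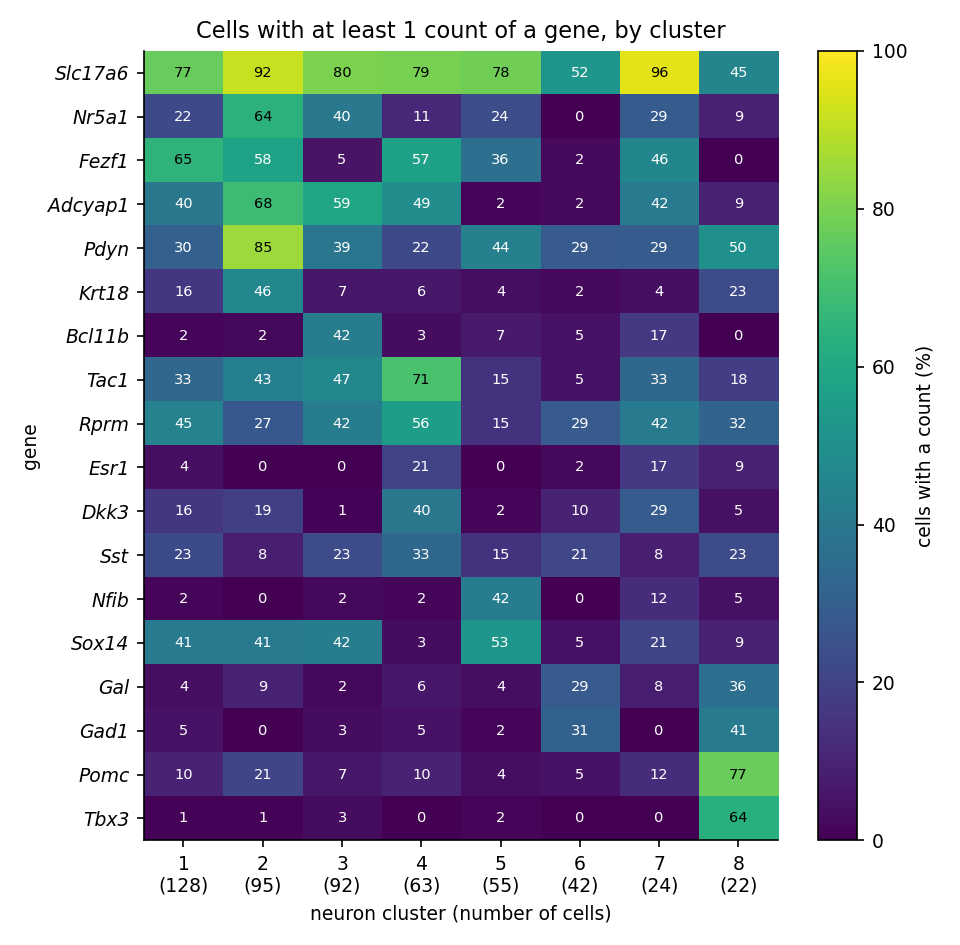
Percent of cells with at least 1 count of each of 18 genes in neuron clusters 1 to 8 (the number of cells is given with each cluster). Nr5a1 was highest in cluster 2 (64.2%), Tac1 in cluster 4 (71.4%) and Pomc in cluster 8 (77.3%).

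The share of a mouse's neurons in each cluster overlapped between the sexes in 8 of 8 clusters. Genes were scaled within each mouse before clustering, which favours like shares, so the overlap does not exclude a difference between the sexes. Cluster 1 held 25.6% ± 8.78 of female neurons and 23.8% ± 5.22 of male neurons (SD, n = 3 mice each; two-sided exact permutation p = 0.9). Cluster 2 held 19.1% ± 10.3 and 17.5% ± 3.79 (exact p = 0.9). In cluster 3, the shares were 19.4% ± 5.23 in females and 16.1% ± 3.86 in males (exact p = 0.4). The Tac1-rich cluster 4 held 13.6% ± 9.82 of female neurons and 10.5% ± 0.620 of male neurons (exact p = 0.7). Its cells numbered 2, 15 and 18 in the females and 9, 9 and 10 in the males. The Nfib cluster 5 held 8.62% ± 2.80 against 12.4% ± 2.30 (exact p = 0.2). The Gad1 cluster 6 held 7.09% ± 0.196 against 9.01% ± 2.24 (exact p = 0.4), and the Pomc cluster 8 held 3.10% ± 4.40 against 5.27% ± 0.850 (exact p = 0.4). Cluster 7 held 3.56% ± 2.08 and 5.43% ± 4.74 (exact p = 0.6). With 3 mice against 3, the smallest two-sided exact p is 0.1, so no share could pass 0.05. At 1000 genes per cell, 1 of 7 clusters had no overlap.

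**Figure D2:**
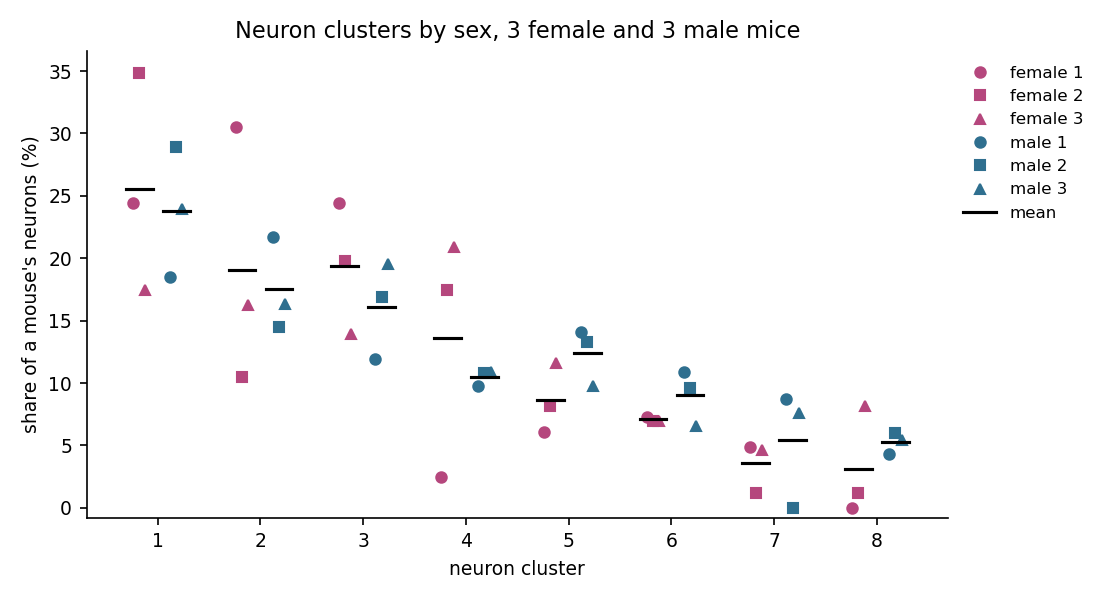
Share of each mouse's neurons (percent) in clusters 1 to 8, females and males; points are mice and bars are means of 3 mice. The female and male points overlap in each cluster.

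Esr1 (GRCm38/mm10 chromosome 10, 4611593 to 5005614) had a count in 25 of the 521 neurons, with 1, 6 and 11 such cells in the females and 1, 2 and 4 in the males. Of these, 13 lay in cluster 4, 20.6% of its cells (exact 95% interval 11.5 to 32.7%), and 4 in cluster 7, 16.7% of its cells (4.74 to 37.4%). Cluster 1 held 5 (3.91%, 1.28 to 8.88%), cluster 8 held 2 and cluster 6 held 1. No cell of clusters 2, 3 and 5 had an Esr1 count, which allows shares of cells with a detected count of up to 3.81, 3.93 and 6.49% and sets no limit on expression below detection. The share of neurons with Esr1 was 6.996% ± 5.79 in females and 2.61% ± 1.64 in males (SD, n = 3 mice each; two-sided exact permutation p = 0.3). It was 4.52% ± 3.61 and 1.18% ± 0.840 after neurons were thinned to 2133 counts. Thinning left out 44 of the 86 neurons of female 2, so thinned shares of that mouse are of its deeper cells only. At 2 counts or more it was 1.18% ± 1.16 and 1.13% ± 0.0680, and without female 3 the difference of -4.38 points was -1.48. Tac1 was detected in 37.9% ± 12.7 of female neurons and 36.4% ± 3.30 of male neurons (exact p = 1). After thinning it was detected in 35.6% ± 1.71 and 25.8% ± 3.16, without overlap (exact p = 0.1, the smallest possible). The Tac1 difference of -1.49 points changed sign without female 1 (1.52), female 3 (2.82) or male 3 (0.409). Rprm was detected in 34.6% ± 2.76 and 39.6% ± 3.36 (exact p = 0.1), a difference of 5.02 points that was -7.03 points after thinning. The thinned Rprm shares were 17.2, 40.8 and 21.8% in females 1, 2 and 3 and 17.7 to 22.2% in males, so that change of sign rests on female 2. Pdyn was detected in 34.1% ± 18.4 and 51.5% ± 7.35 (exact p = 0.3), 17.4 points apart, 7.31 without female 2 and 3.80 after thinning. Nr5a1 was detected in 29.4% ± 19.8 and 30.5% ± 5.57 (exact p = 0.9), 1.09 points apart. The difference was -8.98 without female 2, -1.72 without male 2 and -4.43 after thinning. The progesterone receptor gene Pgr was detected in 7.48% ± 4.07 and 5.19% ± 2.13 (exact p = 0.7), and after thinning in 3.94% ± 0.643 and 1.25% ± 0.510 (exact p = 0.1). The Pgr difference was -0.212 points without female 3 and 0.318 at 2 counts or more. Sst was detected in 16.5% ± 1.25 and 22.8% ± 2.89 (exact p = 0.1). The Sst shares did not overlap after thinning (12.1% ± 0.881 and 15.8% ± 1.02, exact p = 0.1), at 1000 genes or at 2 counts. Its summed level went the other way (1220 ± 783 and 859 ± 576 CPM, with 27.1 to 77.0% of the counts of a mouse in 1 cell), so no order is read from the share. None of the 9 astrocyte-like cells (median 978 counts, against 5972 in neurons) held a count of Esr1, Tac1, Rprm, Pdyn, Sst or Pgr, which allows up to 33.3% of cells with a detected count, and 1 held Nr5a1.

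The labels' sexes were checked with 7 Y-linked genes, which had 1, 0 and 1 counts in the kept cells of the females and 35, 28 and 67 in those of the males. Their summed level was 1.32 ± 1.18 CPM in females and 61.2 ± 22.3 CPM in males (SD, n = 3 mice each; two-sided exact permutation p = 0.1).

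The sex difference was tested in the summed neurons of 3 female and 3 male mice, over 6770 genes, and 0 genes passed an adjusted p of 0.05 in edgeR. The Y-linked translation initiation gene Eif2s3y (chromosome Y, 1010543 to 1028847) had 1 count in female and 77 in male neurons, a ratio of 44.5 with a counting interval of 7.76 to 1781 (adjusted p = 0.451). Its X-linked paralog Eif2s3x, which could share reads with it, was at 92.8 ± 65.7 CPM in females and 59.8 ± 23.3 CPM in males. Ndn (chromosome 7, 62346569 to 62350262), the imprinted gene for necdin, was at 1338 ± 389 CPM in females and 3434 ± 326 CPM in males (log2 fold change, male over female, 1.38, SE 0.246, adjusted p = 0.488). Other values toward males that did not pass were those of the mitochondrial protein gene Hax1 (14.1 ± 21.0 and 75.4 ± 9.31 CPM), the sterol synthesis gene Msmo1 (39.1 ± 38.3 and 146 ± 23.0 CPM) and the RNA-binding protein gene Ybx1 (108 ± 7.37 and 207 ± 47.8 CPM). Toward females, Eif4a2 (chromosome 16, 23107444 to 23114136), an RNA helicase gene of translation initiation with the close paralog Eif4a1, was at 456 ± 226 CPM in females and 76.9 ± 49.7 CPM in males (-2.53, SE 0.482, adjusted p = 0.488). Pdcd10 (chromosome 3, 75516490 to 75556856) was at 90.4 ± 21.6 and 6.56 ± 5.80 CPM (-3.66, SE 0.549, adjusted p = 0.363, the smallest of all genes). The kinase gene Araf (264 ± 277 and 10.9 ± 7.42 CPM), the actin-severing protein gene Dstn (157 ± 98.0 and 23.1 ± 13.4 CPM) and the endoplasmic reticulum channel gene Tmco1 (79.4 ± 16.1 and 25.7 ± 4.65 CPM) were the others of the 5 with the smallest p in that direction. In DESeq2, 6 genes passed: Ndn and Eif2s3y higher in males and Eif4a2, Pdcd10, Dstn and Tmco1 lower. At an unadjusted p under 0.05 there were 159 genes in edgeR and 173 in DESeq2, each below the share of 0.05 of the 6770 genes that chance would give. Since the Y-linked Eif2s3y did not pass in edgeR either, the 0 genes there do not show that the sexes are alike. The sexes did not overlap in 586 genes (8.66%), against 10% by chance. In edgeR, 3 genes passed without female 1, 1 without female 2 and 1 without male 3.

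Among the genes that the study names, Tac1 was at 1028 ± 173 CPM in female and 621 ± 203 CPM in male neurons without overlap (log2 fold change -0.71, SE 0.276). Its unadjusted p in edgeR was 0.0279 and its adjusted p 1.00. Rprm was at 249 ± 161 and 147 ± 46.3 CPM (-0.70) and Nr5a1 at 98.5 ± 58.0 and 64.1 ± 14.4 CPM (-0.63). Pdyn was at 196 ± 126 and 237 ± 45.2 CPM (0.25) and Sst at 1220 ± 783 and 859 ± 576 CPM (-0.49). The steroid dehydrogenase gene Hsd17b12 was at 85.6 ± 13.4 and 103 ± 19.4 CPM (0.27) and the glucocorticoid receptor gene Nr3c1 at 50.9 ± 32.4 and 34.1 ± 14.0 CPM (-0.38). The X-linked Ddx3x, which escapes X inactivation, was at 57.5 ± 4.45 and 33.0 ± 13.9 CPM (-0.75), and Pbdc1 at 48.5 ± 24.8 and 50.9 ± 5.55 CPM (0.03). Without female 2 the sign changed for Pdyn (-0.06), Sst (0.18), Nr3c1 (0.12) and Pbdc1 (-0.16). For Pbdc1 it also changed without female 3 (-0.09) or male 3 (-0.02).

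**Figure D3:**
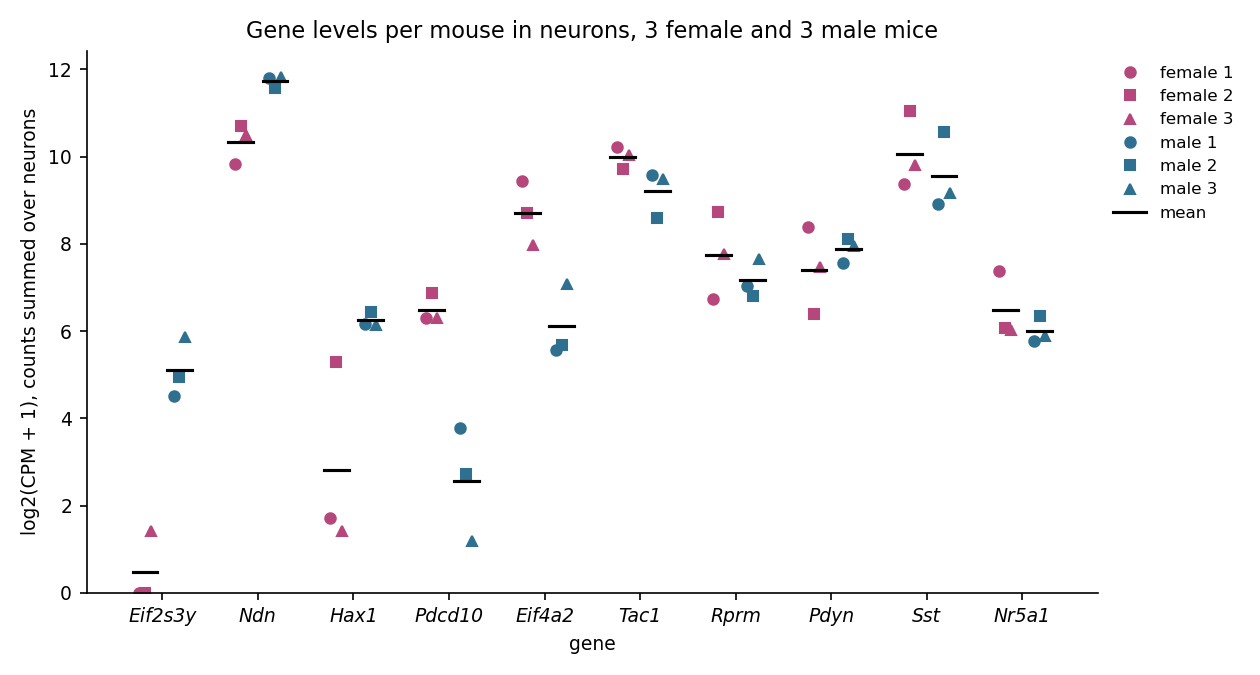
Summed neuron levels of 10 genes per mouse on a log2(CPM + 1) axis, females and males; points are mice and bars are means of 3 mice. Ndn is higher in each male, Eif4a2 and Pdcd10 are lower, and the points of Pdyn, Sst and Nr5a1 overlap.

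Of 15 gene lists tested by camera with a preset correlation of 0.01, 1 passed. The cytosolic ribosomal protein genes were higher in males, under TMM and RLE scaling alike (86 genes, 72 up and 14 down, median log2 fold change 0.21 against -0.03 for all genes, adjusted p = 9.92e-16). With the correlation estimated, the adjusted p was 0.502, and by fry 0.508. Rpl32 (0.65), Rpl41 (0.61) and Rpl23a (0.52), among the members with the smallest p, have many processed pseudogenes, and how reads were split among them is not given in the sources used here. The energy balance signalling genes (1 up and 10 down, adjusted p = 0.0738), the axon growth and guidance genes (14 and 8, 0.107) and the immediate early genes (0 and 5, 0.107) did not pass. Neither did the genes named by the study (1 and 4, adjusted p = 0.113), the oxidative phosphorylation genes (52 and 38, 0.176) and the X-inactivation and escape genes (1 and 2, 0.181). Nor did the VMH identity genes (4 up and 7 down, adjusted p = 0.276), the glutamatergic genes (3 and 6, 0.306) or the voltage-gated potassium channel genes (5 and 5, 0.759). The test pointed up, and the median down, for the neuropeptide and granin genes (median -0.05, mean 0.02, adjusted p = 0.752) and the genes described as sex-dimorphic in adults (median -0.15, mean 0.003, adjusted p = 0.759). So it did for the heat shock genes (median -0.03, adjusted p = 0.759) and the synaptic vesicle genes (median -0.09, adjusted p = 0.859). The sex steroid receptors and enzymes did not pass either (3 genes, adjusted p = 0.759); their test pointed up and their mean (-0.01) down. Adjusted over the list alone, 1 of 1 tested Y-linked gene passed, and 0 members of the other lists did. The ventrolateral VMH and GABAergic lists had 2 tested genes each, 0 up and 2 down, and were not tested as lists. Without 1 mouse, 2 to 4 lists passed. Besides the ribosomal list, the ventrolateral list passed as lower in males without female 1 (adjusted p = 0.00134), male 1 (0.0102) or male 3 (0.0428). The energy balance list passed as lower without female 3 (0.00743), and the immediate early list without female 2 (0.0425) or male 3 (0.0236). The axon growth list passed as higher without female 3 (0.00743) or female 2 (0.0425), and the oxidative phosphorylation list without female 2 (4.03e-05) or male 3 (0.00769). The genes named by the study passed as lower without male 2 (0.0488).

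In the Esr1-undetected neurons, 0 of 6421 genes passed in edgeR (148 at an unadjusted p under 0.05, smallest adjusted p 0.514), and 4 passed in DESeq2 (163 unadjusted). Ndn was at 1353 ± 400 CPM in females and 3437 ± 320 CPM in males (1.37), Eif4a2 at 462 ± 223 and 77.1 ± 48.1 CPM (-2.55) and Pdcd10 at 86.6 ± 22.4 and 6.70 ± 5.89 CPM (-3.55; SD, n = 3 mice each). The log2 values of the other genes were 3.02 for Hax1, 1.00 for Ybx1, -4.56 for Araf, -1.57 for Tmco1 and -2.74 for Dstn. The kinase gene Brsk2 was at 5.71 ± 3.64 and 23.1 ± 1.64 CPM (2.05). Tac1 was at 864 ± 290 and 636 ± 211 CPM (-0.42), with the sexes overlapping. Its unadjusted p in edgeR was 0.209. Log2 values were -0.57 for Rprm, 0.16 for Pdyn, -0.59 for Sst, and -0.66 for Nr5a1. They were 0.22 for Hsd17b12, -0.38 for Nr3c1, -0.66 for Eif2s3x, -0.81 for Ddx3x and 0.003 for Pbdc1. Without female 2 the sign changed for Rprm (0.08), Pdyn (-0.15), Sst (0.06), Nr3c1 (0.05) and Pbdc1 (-0.21), and for Pbdc1 also without female 3 (-0.12) or male 3 (-0.06). Groups without overlap numbered 575 (8.95%), against 10% by chance. In edgeR, 4 genes passed without female 1, 1 without female 2 and 1 without male 3.

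Within clusters, the sex difference was tested in clusters 1, 2, 3, 5 and 6, which held at least 5 cells of every mouse, and 2 of 8386 gene and cluster pairs passed in edgeR (255 at an unadjusted p under 0.05). In the Nfib cluster 5, Ndn was at 923 ± 43.0 CPM in females and 4590 ± 187 CPM in males (SD, n = 3 mice each; log2 fold change 2.30, SE 0.216, adjusted p = 6.09e-05), higher in 3 of 3 males than in any female. In the Pdyn-rich cluster 2, Eif4a2 was at 557 ± 190 CPM in females and 71.5 ± 31.1 CPM in males (-2.96, SE 0.391, adjusted p = 0.0322), lower in 3 of 3 males. The adjusted p of Eif4a2 was 0.139 without female 1, 0.267 without male 1 and 0.167 without male 2, and ranged over the alternatives from 2.82e-09 to 0.593. Ndn was also at 1293 ± 618 and 3417 ± 592 CPM in cluster 1. It was at 1224 ± 364 and 3429 ± 407 CPM in cluster 2 (adjusted p = 0.0619) and 1527 ± 257 and 3549 ± 412 CPM in cluster 3 (adjusted p = 0.421), none of which passed. In cluster 2, Ndn had an adjusted p of 0.0191 without female 2, in a range of 1.08e-07 to 0.593. The ubiquitin ligase adaptor gene Klhl13 (77.5 ± 36.3 and 247 ± 62.8 CPM) and Dstn (183 ± 39.5 and 24.5 ± 23.9 CPM) in cluster 2 did not pass. Eif4a2 in cluster 3 (551 ± 353 and 90.8 ± 44.5 CPM), the growth cone gene Basp1 in cluster 5 (1509 ± 695 and 553 ± 157 CPM) and Sst in cluster 1 (438 ± 286 and 81.3 ± 34.6 CPM) did not pass either. Basp1 had an adjusted p of 0.0208 without female 1, the lowest of its range, which reached 0.997. DESeq2 gave 9 pairs, and edgeR gave 7 without female 1, 6 without female 2 and 1 without male 1 or male 2. Differences between clusters in these sex differences were not tested.

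**Figure D4:**
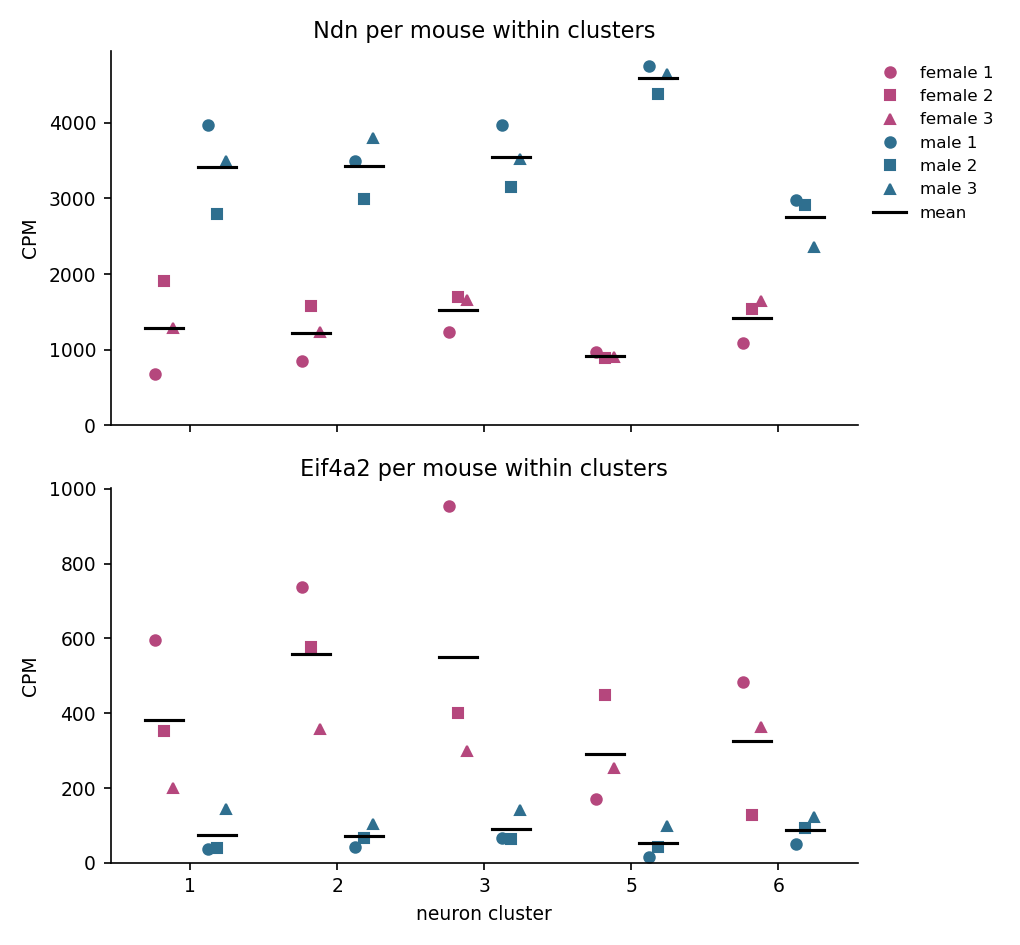
Ndn and Eif4a2 (CPM) per mouse in neuron clusters 1, 2, 3, 5 and 6, females and males; points are mice and bars are means. Ndn in cluster 5 (means 923 and 4590 CPM) and Eif4a2 in cluster 2 (means 557 and 71.5 CPM) passed the test.

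Esr1-detected and Esr1-undetected neurons were compared within the 6 mice over 3831 genes, and 19 passed in edgeR, 5 higher with Esr1 and 14 lower (376 at an unadjusted p under 0.05). The peptide gene Cartpt (chromosome 13, 99898489 to 99901091) was at 62.7 ± 21.4 CPM without Esr1 and 554 ± 888 CPM with it (SD, n = 6 mice; higher in 3 of 6; log2 fold change 2.55, adjusted p = 6.74e-11). The protocadherin gene Pcdh17 was at 129 ± 42.1 and 408 ± 257 CPM (5 of 6 mice; adjusted p = 1.36e-05). Igfbp5 (46.6 ± 22.8 and 197 ± 241 CPM, 5 of 6 mice), Parm1 (34.4 ± 16.9 and 122 ± 102 CPM, 4 of 6) and the homeodomain gene Isl1 (55.8 ± 15.03 and 107 ± 189 CPM, 2 of 6) were also higher. The p-values of this edgeR fit match a normal test of the fold change over its SE. A gene's own spread between mice hardly enters them, so Cartpt and Isl1 could pass though higher in 3 and 2 of 6 mice. Lower in each of the 6 mice were the metallothionein genes Mt1 (chromosome 8, 94179082 to 94180327; 295 ± 94.9 and 70.9 ± 125 CPM; -2.87, SE 0.506, adjusted p = 1.36e-05) and Mt3 (664 ± 120 and 263 ± 100 CPM; -1.45, adjusted p = 8.03e-04). The aldolase gene Aldoc (chromosome 11, 78322968 to 78327781) was at 533 ± 111 and 158 ± 110 CPM (-1.68, SE 0.335, adjusted p = 3.45e-04). The channel-interacting protein gene Kcnip1 was at 234 ± 43.7 and 56.3 ± 65.5 CPM and A230065H16Rik at 220 ± 53.5 and 43.6 ± 101 CPM. The mitochondrial protein gene Chchd10 was at 1419 ± 351 and 878 ± 365 CPM, and the polyubiquitin gene Ubb at 6155 ± 581 and 4723 ± 852 CPM. The Esr1-detected sum of female 1 was 1 cell of 3136 counts. For genes at the level of Mt1 or below, a 0 in that sum may be counting error alone. Among such genes the condition of 1 direction in all 6 mice is met more readily by lower than by higher genes. Arhgap36 had 209 counts without Esr1 (in 105 cells) and 0 with it, 3.47-fold lower against a floor of 3 counts over the group. The exact counting interval of its ratio starts at 2.79. Npy had 223 and 0, but 11 cells held its counts, 172 of them in 3 cells. At the shares of each mouse, 0.326 Esr1-detected cells with Npy would be expected, so no fold is read from the 0. The neurotensin gene Nts had 252 counts in 39 cells and 1 count, where 2.09 cells with Nts would be expected. Sst (-1.48), Calb2, Lypd1 and Atraid were the other lower genes, and Tac1 was at -0.12 (-1.73 to 1.15 over the alternatives, passing only at 1.15, in the mice with at least 4 Esr1-detected neurons). DESeq2 gave 17 genes, 12 higher and 5 lower. With RLE size factors edgeR gave 25, of which 15 were higher and 10 lower, against 5 and 14 with TMM, and the median log2 fold change of all genes moved from -0.18 to 0.09. Relative to that shift Mt1 (-2.60), Mt3 (-1.13), Aldoc (-1.40) and Sst (-1.04) stayed lower and Cartpt (2.90) higher. The adjusted p of Cartpt in DESeq2 was 0.806, in a range of 4.13e-16 to 0.806. Mt1 and Aldoc passed in every alternative run, with highest adjusted p of 0.0240 and 0.0425. The Esr1-detected sums held 156404 counts in all, against 3143890, and 2 of the 6 mice had at least 5 Esr1-detected cells. The comparison was not matched by cluster. Without female 3, which held 11 of the 25 cells, 7 genes passed. The adjusted p without it was 0.0908 for Igfbp5 and Kcnip1, 0.713 for Parm1 and 0.220 for A230065H16Rik. Further losses without 1 mouse were Igfbp5 (male 1, 0.412), Isl1 (female 2, 0.0518, and male 3, 0.101), Kcnip1 (male 2, 0.106) and Chchd10 (male 2, 0.0745). The call was also lost for Arhgap36 (male 1, 0.113, and male 3, 0.102), Nts (female 2, 0.0583, and male 3, 0.134) and Ubb (5 of 6 mice, 0.0779 to 0.274). Over all alternatives the adjusted p reached 0.0766 for Pcdh17, 0.103 for Mt3, 0.314 for Chchd10, 0.339 for Kcnip1 and 0.412 for Igfbp5. It reached 0.713 for Parm1, 0.415 for Ubb, 0.458 for Nts, 0.540 for Arhgap36 and 0.992 for Isl1. The call for Sst was lost in DESeq2 (adjusted p = 0.482), after thinning (0.587) and without female 3 (0.0908), in a range of 1.94e-16 to 0.587. Calb2 lost it after thinning (0.172), and Lypd1 there, in DESeq2 and without female 3 (highest 0.552). Npy passed in 3 of 11 alternatives (highest 0.992) and Atraid in 5 of 13 (0.642), and each lost the call without 4 or more of the 6 mice in turn.

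By Esr1 detection, 3 of 12 lists passed in camera with the preset correlation, each lower with Esr1. These were the cytosolic ribosomal protein genes (1 up and 84 down, median log2 fold change -0.35, adjusted p = 5.34e-12), the oxidative phosphorylation genes (5 and 79, -0.38, 7.88e-12) and the neuropeptide and granin genes (3 and 15, -0.39, 0.0295), against a median of -0.18 over all genes. The size of these shifts and the number of lower members depend on the scaling. With RLE size factors the medians were -0.03, -0.05 and -0.05, still below the 0.09 over all genes. Then 34, 33 and 7 genes were up and 51, 51 and 11 down. With the correlation estimated, these adjusted p were 0.279, 0.243 and 0.243, and by fry 0.206, 0.206 and 0.263. The members with the smallest p were Rpl22 (-1.56), Rplp1 (-0.55), Rps3a1 (-0.59) and Rps13 (-0.60) of the ribosome and Cartpt, Sst, Npy and Nts among the peptides. Of oxidative phosphorylation they were Atp5h (-0.89), Cox6a1 (-0.78) and Ndufs7 (-1.02) with Cox6a2 (3 counts, a ratio of 5.01 with a counting interval of 1.70 to 24.4). Lists that did not pass were the heat shock genes (0 up and 9 down, adjusted p = 0.0509), the genes named by the study (1 and 4, 0.0585) and the genes described as sex-dimorphic in adults (3 and 0, 0.0585). The VMH identity genes (3 and 5, 0.376), the axon growth and guidance genes (4 and 12, 0.376), the energy balance signalling genes (2 and 4, 0.739), the voltage-gated potassium channel genes (2 and 2, 0.742), the glutamatergic genes (2 and 3, 0.916) and the synaptic vesicle genes (9 and 8, 0.916) had higher adjusted p. Adjusted over the list alone, 8 of 18 neuropeptide and granin genes passed, 4 of 8 VMH identity genes, and 6 of 84 oxidative phosphorylation genes. So did 2 of 5 glutamatergic genes, 1 of 3 sex-dimorphic genes, 1 of 4 potassium channel genes and 4 of 5 genes named by the study, which are not independent evidence. Without 1 mouse, 2 to 5 lists passed, and the neuropeptide list did not pass without female 1, female 3, male 1 or male 2. The heat shock list passed without female 2 (adjusted p = 0.00473) and female 3 (0.0450), and the genes named by the study without female 2 (0.0279) and female 3 (0.0288). The axon growth list passed without female 3 (0.0379) and the sex-dimorphic list without male 1 (0.0244) and male 2 (0.0336).

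The sex difference within Esr1-detected neurons was set to need 5 such cells in every mouse, which 2 mice had, so it was not run. Whether the sex difference differed between Esr1-detected and Esr1-undetected neurons was tested as an interaction over 3831 genes, and 3 passed in edgeR (85 at an unadjusted p under 0.05). Tac1 (chromosome 6, 7554879 to 7565834) was at 319, 2360 and 3324 CPM in the Esr1-detected neurons of the females, from 1, 29 and 286 counts. It was at 0, 147 and 0 CPM in those of the males, from 0, 2 and 0 counts. In the Esr1-undetected neurons Tac1 was at 1197, 736 and 660 CPM in females and 775, 394 and 739 CPM in males. The interaction was -5.47 (log2, SE 0.847, adjusted p = 4.14e-07 in edgeR). The p-values of this fit also match a normal test of the change over its SE, so a gene's own spread between mice hardly enters them. Summed over mice, Esr1-detected neurons held Tac1 at 3115 CPM in females and 36.4 CPM in males, a ratio of 85.6 with a counting interval of 23.5 to 710. Without female 3 the female level was 1945 CPM (30 counts), and without male 3 the ratio was 42.0. Of the Esr1-detected cells, 13 of 18 in females and 1 of 7 in males held Tac1 (77.3% ± 25.3 and 16.7% ± 28.9 per mouse, n = 3 each, exact permutation p = 0.2). Cartpt was at 98.6 CPM in females (10 counts) and 928 CPM in males (51 counts) in the Esr1-detected neurons, a ratio of 9.42 (4.73 to 20.8). Of the 51 counts, 31 were in 2 cells of male 2, without which the male level was 484 CPM and the ratio 4.91, and without female 3 the ratio was 4.77. In the others it was at 77.6 and 44.7 CPM (interaction 3.79, SE 0.696, adjusted p = 1.01e-04). Ap1s2 (chromosome X, 163909017 to 163933666), a subunit gene of the AP-1 adaptor complex, was at 78.9 CPM (8 counts) and 710 CPM (39 counts), with a counting interval of the ratio of 4.15 to 22.3. In the others it was at 185 and 195 CPM (interaction 3.20, SE 0.745, adjusted p = 0.0223). For Tac1 and Cartpt the mice of the sexes overlapped in their change with Esr1. Values that did not pass were those of Sst (2.31, adjusted p = 0.339), the G protein gene Gnb4 (1 count in females and 11 in males with Esr1, a ratio of 20.3, 2.95 to 874), and Lypd6 (0 and 8 counts, the latter in 2 cells). Toward females they were those of the diacylglycerol kinase gene Dgkk (15 counts in 5 cells, and 0), Slc25a46 (15 counts, all in 1 female, and 0), Gna11 (11 and 0 counts) and Parm1 (227 and 72.8 CPM). Against a floor of 3 counts Gna11 was 1.99-fold lower in males, and the counting interval of its ratio starts at 1.36. DESeq2 gave 0 genes (59 unadjusted), with adjusted p of 0.999 for Tac1, 0.999 for Cartpt and 0.105 for Ap1s2. Over the alternatives, the adjusted p ranged from 7.11e-18 to 0.999 for Tac1, 1.25e-07 to 0.999 for Cartpt and 4.37e-05 to 1 for Ap1s2. Without each mouse in turn 1 to 4 genes passed, 1 without female 3. The adjusted p of Tac1 reached 0.00774 without female 3, and that of Cartpt 0.454 without female 3 and 0.0773 without male 2. That of Ap1s2 was 0.430 without female 2, 1.00 without female 3, 0.111 without male 1 and 0.0982 without male 3.

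**Figure D5:**
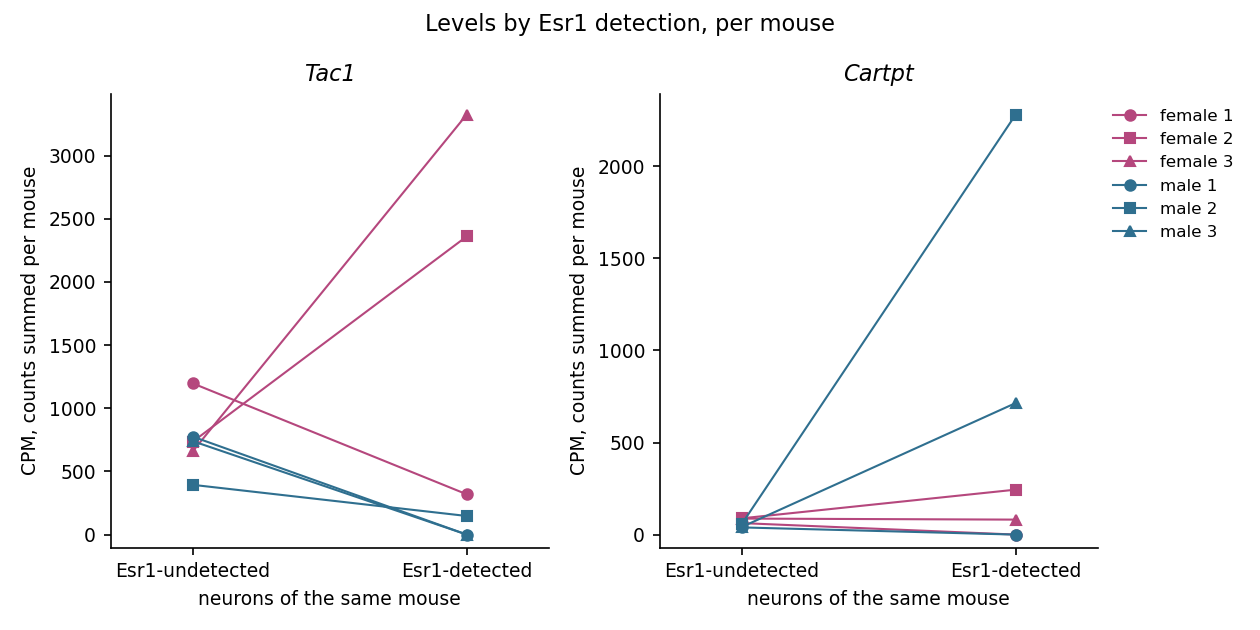
Tac1 and Cartpt (CPM) per mouse in Esr1-undetected and Esr1-detected neurons, females and males; a line joins the sums of 1 mouse. Tac1 in Esr1-detected neurons was at 319 to 3324 CPM in the females and 0 to 147 CPM in the males.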

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

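The counts of other splits of the mice were chosen as tests after the results were seen, and voom with quality weights was an alternative added after seeing the data. Tac1, Cartpt and Ap1s2 stand here because their sex difference itself differed between Esr1-detected and Esr1-undetected neurons, and the last paragraph holds signals in cells and wells that no comparison used.

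In Esr1-detected neurons Tac1, the substance P precursor gene, was at 3115 CPM in females and 36.4 CPM in males, while in the other neurons it was at 881 and 664 CPM (interaction -5.47, adjusted p = 4.14e-07 in edgeR). A single mouse as the whole cause of the call is argued against, since the adjusted p without each mouse in turn reached at most 0.00774. These fits do not show a change shared by the females. Without female 3, 29 of the 30 female counts were from female 2, and female 1 had 1 count in 1 cell. The mice of the sexes overlapped in their change with Esr1. Another share of the Tac1-rich cluster 4 among the Esr1-detected cells of females may contribute: that share was 12.7 points higher in females, with an interval of -26.1 to 46.3 points, so 18 and 7 cells are too few to decide. Makeup beyond cluster 4 differed as well. Cluster 1 held 5 of the 18 female and 0 of the 7 male cells, and clusters 6, 7 and 8 held 3 and 4. Mean Tac1, over mice with at least 5 cells, was 707 CPM in cluster 1 and 78.7 and 14.3 CPM in clusters 6 and 8. In cluster 7 it was at 77.2 and 480 CPM in males 1 and 3. In females 1 and 3 (4 cells each) it was at 1196 and 916 CPM there. Esr1-detected cells of cluster 7 with Tac1 numbered 2 of 2 in female 3 and 0 of 1 each in males 1 and 3. In cluster 4 they numbered 2 of 3 in female 2, 6 of 7 in female 3, 1 of 2 in male 2 and 0 of 1 in male 3. A dependence of Tac1 on sex in neurons that express Esr1 stays open and was not tested apart from the fit itself. DESeq2 gave an adjusted p of 0.999, and 286 of the 316 female counts came from female 3.

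Cartpt changed the other way (interaction 3.79, adjusted p = 1.01e-04), and so did Ap1s2 (3.20, adjusted p = 0.0223); neither passed without female 3 (0.454 and 1.00, in ranges of 1.25e-07 to 0.999 and 4.37e-05 to 1). The 10 splits of the 6 mice are too few for a share under 0.05; 1 split, the real one, gave 3 genes, and the highest of the others gave 2.

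The wells left out by the cell filter held 4640 counts, of which 3595 were in 8 wells of female 1 (median 498 counts per well), and they held 0 counts of Esr1 and 1 of Tac1. Outside the neuron clusters, 9 of 9 cells held Apoe, 8 Agt and 7 each Gja1 and Slc1a3; 6 of these cells were from female 1.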

How the results depend on the processing

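The library group term, the other neighbour numbers, the clustering without scaling, the quality weights and leaving out mice within clusters were chosen after seeing the data. Where no construction shows it, the cause was not tested. Each value was counted once per alternative setting. Of counts and share differences that answer a comparison, 105 stayed the same, 43 moved and 10 reversed. Here a count stayed the same within 1.5-fold, and a share difference by keeping its sign. Of values of named genes and pairs, 811 kept sign and side of the threshold, 49 newly passed, 59 no longer passed and 25 reversed. The 1 other value, a count of genes passing within a cluster, moved.

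Genes passing by sex in neurons (0) numbered 6 in DESeq2, 24 with no filter on low counts, 1 by limma on mean log2 values (Ndn), 1 with a library group term (Araf; female 1 and males 1 and 2 against female 3 and male 3, female 2 left out) and 0 to 3 without 1 mouse. In Esr1-undetected neurons (0) they numbered 4, 26 and 0 to 4 for DESeq2, no filter and without 1 mouse. The interaction (3) gave 0 in DESeq2 and 1 to 4 without 1 mouse. The Esr1 comparison (19, of which 5 higher and 14 lower with Esr1) gave 167 with no filter (7 and 160), 7 with detection called after thinning (2 and 5), 194 with voom quality weights (162 and 32) and 7 to 25 without 1 mouse. The balance of higher and lower genes thus depends on the tool. The setting with the library group term also leaves out female 2, and without female 2 alone the genes in neurons numbered 1, the pairs 6 and the lists by sex 4. Pairs within clusters (2) numbered 1 at resolution 1.5, 9 in DESeq2, 29 with no filter, 4 with the library group term and 1 to 7 without 1 mouse; no filter tests more genes, at 60460 pairs against 8386. Lists by sex (1) numbered 0 with estimated correlation, 0 by fry, 4 with the library group term and 2 to 4 without 1 mouse, and lists by Esr1 (3) 0, 0 and 2 to 5 for estimated correlation, fry and without 1 mouse. Clusters whose shares did not overlap (0) numbered 1 at 1000 genes per cell, 1 with 8 nearest neighbours and 0 at the other settings.

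Differences in detection shares (male minus female, points) reversed for Rprm after thinning (-7.03), for Nr5a1 after thinning (-4.43), at 1000 genes (-0.235) and at 2 counts (-0.421), and for Pgr at 2 counts (0.318). Without 1 mouse they spanned -8.80 to 2.82 for Tac1, -8.98 to 10.8 for Nr5a1, -7.27 to -1.48 for Esr1, 7.31 to 25.3 for Pdyn and -4.28 to -0.212 for Pgr. Log2 values in neurons reversed with female 2 left out and the library group as a term for Pbdc1 (-0.17), Rprm (0.068), Pdyn (-0.069), Sst (0.082) and Nr3c1 (0.18). Leaving out female 2 alone reversed all of these but Rprm, at -0.16, -0.058, 0.18 and 0.12. Values reversed by limma on mean log2 values for Rprm (0.12), Sst (0.53) and Nr3c1 (0.14), where the median of all genes was 0.54, and with thinned cells for Sst (0.89). Without 1 mouse they spanned -0.16 to 0.49 for Pbdc1, -0.058 to 0.83 for Pdyn, -1.18 to 0.18 for Sst and -0.69 to 0.12 for Nr3c1. In Esr1-undetected neurons Sst reversed with thinned cells (0.81) and with detection after thinning (0.31), and so did Pbdc1 with the latter (-0.068). Without 1 mouse they spanned -0.21 to 0.49 for Pbdc1, -0.93 to 0.076 for Rprm, -0.15 to 0.66 for Pdyn, -1.25 to 0.055 for Sst and -0.71 to 0.051 for Nr3c1.

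No pairing of the sexes by mouse number was seen, though so few pairs cannot decide it. After the mean of each sex was taken out of every gene, females and males of the same number correlated at -0.128, -0.0883 and 0.155. Those of different numbers correlated at -0.0953 to 0.206. With the number as a block, 0 genes passed in neurons (138 unadjusted), 0 in Esr1-undetected neurons (135 unadjusted), 1 pair within clusters (Ndn in cluster 5, adjusted p = 0.00150, while Ndn and Eif4a2 in cluster 2 were at 0.593) and 5 lists by sex. Not run were the sex difference in Esr1-detected neurons with its alternatives, and the cluster-matched Esr1 comparison, since 0 clusters held both kinds of cell in every mouse. Depth limited female 2 most, at 185654 counts.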

Other observations

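The tests of splits, of random sets of cells and of expected counts, of gaps within a sex, and the tests in cluster 4, were chosen after the results were seen. In the 521 neurons, Sst and Cartpt were detected together in 27 cells where 11.6 would be expected by independence, Tac1 and Rprm in 87 (71.6) and Pdyn and Nr5a1 in 91 (72.8). Esr1 was detected with Cartpt in 8 cells (3.21), with Rprm in 15 (9.37) and with Tac1 in 14 (9.41). Fewer than expected held Nr5a1 with Cartpt (9 against 17.3), Esr1 with Nr5a1 (2 against 6.56) and Sst with Pgr (2 against 6.20). Bdnf was detected in 78.9% of cluster 2 and 68.3% of cluster 4 cells, Cbln1 in 82.1% and 76.2%, and Npy2r in 63.6% of cluster 8 cells. Pomc, in 77.3% of cluster 8 cells, also had a count in 21.1% of cluster 2 cells, at 26.1 ± 8.50 CPM against 11072 ± 2844.

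Ndn was higher in the mean of the males in clusters 1 to 6, by 1.40, 1.49, 1.22, 1.12, 2.31 and 0.95 on the log2 scale, and Eif4a2 was lower, at -2.38, -2.96, -2.60, -2.63, -2.49 and -1.87; 2 of these 12 values passed a test in the main comparison. In cluster 8, with 1 female and 2 males, the values were 0.44 for Ndn and 0.43 for Eif4a2, so Eif4a2 went the other way there (92.4 CPM, and 124 ± 141 CPM in the males), and in cluster 7 no female had enough cells for a mean. In cluster 4, tested with 6 mice, 0 of 1463 genes passed in edgeR (31 unadjusted; no other tool was run there), and without female 1, which held 2 of its cells, 2 of 1774 passed (56 unadjusted).

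Some genes were abundant in 1 mouse and nearly absent from another: 31 of 1287 genes with at least 200 CPM in a mouse were at least 16-fold lower in another, with the lowest value in female 2 for 15 of them. Eif4a1 was at 5.49 CPM in female 2 against 461 to 559 CPM in the others, Aes at 11.0 against 507 to 618, and Araf and Dstn were among the 31. The depth of the lowest library as the cause is argued against, since a median of 55.4 counts was expected there. So is sex as their common cause, since 29 of the 31 (93.5%, exact 95% interval 78.6 to 99.2%) had a 16-fold gap between 2 mice of the same sex. With counts of 0 set to 1 count, the sexes did not overlap for 5 of the 31, Araf and Dstn included. Parpbp, also among the 5, had counts in female 3 alone, so its CPM overlap and it holds no order of the sexes. For Dstn, without such a gap within a sex, sex stays open. A different makeup of cell types could not be excluded for the 31 genes as a set. Of them, 58.1% kept an 8-fold gap within each of clusters 1, 2 and 3. The exact 95% interval of 39.1 to 75.5% spans the bound of 50% set for excluding it. For the 18 genes that kept the gap, it argues against the shares of these clusters as the whole cause. Eif4a1 kept gaps of 39.7, 18.4 and 15.5-fold and Aes of 40.7, 17.3 and 23.2-fold, with counts of 0 set to 1 count. Differences in how libraries were made or counted may contribute and were not tested.

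The Esr1-detected sums rest on 1 to 11 cells per mouse, so the number of calls may come from the choice of few cells. Of 20 random sets of Esr1-undetected neurons of like number and depth, 0 gave 19 genes or more (at most 6). This argues against a random choice of few cells as the source of the count of genes. The sets were not matched by cluster. Cluster 4 held 13 Esr1-detected and 50 undetected neurons, and clusters 2, 3 and 5 held 0 detected. Cartpt and Parm1 were among the leading genes of cluster 4 and A230065H16Rik of cluster 2, but Nts, lower with Esr1, also led cluster 4. The makeup of clusters may thus contribute and was not tested. For the lists, 19 of the 20 sets gave 3 or more (2 to 7), so the count of lists is within what few cells give. Of the 32 swaps within mice, 1, the real one, gave 19 genes, with 7 the highest of the others, and 13 gave 3 lists or more (highest other 5). Only the real labelling sets the small sum of every mouse on the same side. The swaps therefore cannot separate an effect of small sums from one of Esr1, and they exclude nothing.

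For the comparisons by sex, the 10 splits of the 6 mice are too few for a share under 0.05. The real split gave 0 genes in neurons and 0 in Esr1-undetected neurons. Each of the 10 splits reaches a count of 0 whatever the data, so these counts of splits decide nothing. The highest other split gave 4 genes in each, and set female 1 with males 1 and 2. Within clusters it gave 2 pairs, with 5 splits at as many and 3 the highest other, and for lists 1, with 7 splits at as many and 5 the highest other.

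Summed over marker lists in neurons, females and males had 12915 ± 1309 and 12938 ± 754 CPM of pan-neuronal genes (SD, n = 3 mice each; exact permutation p = 1), 1423 ± 292 and 1391 ± 201 of VMH genes (0.9). They had 137 ± 49.3 and 79.5 ± 35.1 CPM of GABAergic genes (exact p = 0.2) and 697 ± 624 and 731 ± 387 of arcuate genes (1). Glial lists were at 605 ± 191 and 517 ± 61.0 CPM for astrocytes (exact p = 0.8), 104 ± 10.8 and 72.5 ± 14.2 for oligodendrocytes (0.1, without overlap) and 32.2 ± 55.7 and 3.19 ± 1.70 for their precursors (1). They were at 18.7 ± 13.3 and 13.4 ± 7.54 for microglia (exact p = 0.7) and 43.5 ± 9.53 and 38.1 ± 9.22 for tanycytes and ependymal cells (0.5). Endothelial (49.0 ± 21.1 and 33.2 ± 12.2 CPM, exact p = 0.3), mural (7.85 ± 3.97 and 5.25 ± 4.78, 0.6), fibroblast (8.32 ± 6.81 and 2.33 ± 1.33, 0.2), erythroid (0 and 1.48 ± 1.33, 0.4) and pituitary lists (424 ± 692 and 542 ± 362, 0.8; Pomc included) overlapped. Of the 1196 counts of Pmch in female 3, 1195 were in 1 cell, and of the 56 of Npy and 39 of Agrp in female 2, 55 and 38 were in 1 cell. Female 2 correlated with the other mice at 0.782 to 0.832, and the others among themselves at 0.889 to 0.925.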
